A study of Homo sapiens with 16 samples.

How the data were processed

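Total RNA was sequenced from ES-2, an established human ovarian cancer cell line, and from clones of it that had been selected for resistance to AZD1775, an inhibitor of the Wee1 kinase. The 16 libraries fell into 6 groups: untreated parent (n = 2), parent given 100 nM drug for 24 h (n = 2), and 4 clones (n = 3 each). Per the labels' protocols, clones were picked as single colonies under drug and expanded with the drug present, RNA was taken at 70% confluency from replicate cultures, and stranded libraries were made after depletion of ribosomal RNA. The replicates of a group were therefore separate cultures of one line or clone, and the p-values measure the spread between such cultures, not between independently derived clones.

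The authors' deposited gene table held expected counts (estimated counts that need not be whole), made with Salmon 0.10.2 on build hg38 per the submitters' processing notes. The annotation was not given in the sources used here. The per-library files held, per the file headers, estimated counts, TPM and effective length for each transcript. Recomputing the gene table from those files showed that 98.8% of values above 50 matched length-scaled TPM within 0.01 on the log2 scale, against 21.05% for plain sums of transcript counts. A gene count therefore carried a correction for transcript length, and a change in isoform usage moved it less than it would move a plain sum. The authors also deposited variance-stabilised values on a log2 scale, with a shared floor of 3.39 for genes without counts. Those values were used only in one alternative fit. The design had allowed for whole or expected counts, and expected counts were rounded to whole numbers before testing. Every column of the tables belonged to one of the 16 libraries.

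Of 57914 genes in the table, 57653 were in GENCODE 29, as were 199415 of 199658 transcripts, and gene symbols and GRCh38 coordinates were taken from that release. Total expected counts ran from 47500243 to 63553348 per library, and 41112 genes had a count in at least 1 library. At these depths, 3 counts per library was taken as the floor below which a gene was not detectable. Where all libraries of a group had 0 counts, a fold was computed against that floor and is a lower bound. Where a group held 1 to 3 counts in all, the ratio of the summed CPM (counts scaled to library size) is given with a 95% interval. Floors and intervals cover counting error only, since the reads carried no molecular identifiers.

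The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM factors, the default expression filter and 1 mean per group in a single fit of all 16 libraries. The filter left 21724 genes, the common dispersion was 0.00873 and the prior degrees of freedom were 6.64. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and an adjusted p under 0.05 was a call. Levels are mean CPM per group, changes are log2 fold changes ± SE from the fit, and a fold of a low gene depends on the prior count of the fit. Pairs of libraries of a group differed by 5.67 to 46.5 times the variance of pure counting (chi-square per degree of freedom), so no library had been deposited more than once.

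The design, the named-gene rule, 33 gene lists and the alternatives below were chosen before the data were examined. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 33 lists within a comparison. For each list the members called over all genes were counted, and the members called when p was adjusted over the list alone. Named genes were 10 genes around Wee1 signalling and drug efflux that are always given, and the 8 largest rises and 8 largest falls per comparison. The latter had to be called, to have a mean count of at least 100 in the higher group, and to show no overlap between replicates. For the contrasts between lineages the 5 largest each way were taken, and 2 to 4 members of each described list came in order of adjusted p. For genes called the same way in all 4 clones, the 8 with the largest smallest change were taken in each direction.

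Comparisons that share the untreated parent libraries share their chance values. Overlaps between pairs of them are given beside those expected of independent lists, and beside 20 simulated sets of unchanged groups against the same controls. The 2 untreated libraries were not split between the clones, which would have left 1 control per comparison. Shifts of whole chromosomes were measured over 11977 protein-coding genes with a mean of at least 1 CPM, in bins of 10 Mb.

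The procedure was tested on simulated counts with 200 changed genes, all with a mean above 1 CPM and changed in a single group. The rates therefore do not cover less expressed genes, or scaling when as many genes change as in the clones. For the treated against the untreated parent, 59.7% of 1.5-fold, 83.6% of 2-fold and 100% of 4-fold changes were recovered among 20928 genes, and 7.4% of the calls were false. For clone 250:3 against the parent, with 20956 genes, 67.2%, 85.1% and 98.5% were recovered and 4% of the calls were false. For the 1000 nM clone from 250:3 against its progenitor, with 20951 genes, 83.6%, 91% and 100% were recovered and 4.7% were false. For the difference between lineages, with 20950 genes, the recovered shares were 55.2%, 83.6% and 97%, with 6% false.

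The alternatives tried were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma on the variance-stabilised values, a fit of only the libraries compared, transcript sums with a length offset, library numbers 1 to 8 against 9 to 16 as a covariate, and the treated parent as reference. Each library was also left out in turn. Leaving genes of chromosomes with shifted expression out of the counts, without a new fit, was an alternative added after seeing the data. Sequence variants and transcript usage were not analysed here. Some members of the gene lists are not reported here by name. Counts of multi-copy families such as SPANX, MAGE, histone and HLA genes depend on how Salmon divides reads among near-identical copies, so values of single members are uncertain, as are those of overlapping genes.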

Results

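RNA of ES-2, an established human ovarian cancer cell line, was sequenced before and after exposure to the Wee1 kinase inhibitor AZD1775 and after selection for resistance to it. The untreated parent line and the parent given 100 nM drug for 24 h were each represented by 2 cultures. Clones 250:3 and 250:7 had been selected at 250 nM, and a further clone named 1000:2 had been derived from each of them at 1000 nM, with 3 cultures per clone. The 16 libraries held 47500243 to 63553348 expected counts each. Unless stated otherwise, levels are group means in CPM (counts scaled to library size), changes are log2 fold changes ± SE, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 21724 genes. A "call" is an adjusted p under 0.05. Replicates of each group lay together in a principal component analysis, in which the first component held 38.4% and the second 23.3% of the variance. Both clones of the 250:7 lineage lay at 67.7 to 78.2 on the first component, and both clones of the 250:3 lineage at -85.3 to -40.5. Small structural RNAs took 9.27% ± 0.438 of counts in the untreated parent (SD, n = 2), 8.87% ± 0.346 in the treated parent (n = 2), and means of 10.7% to 12.3% in the clones (n = 3 each). Library 6 of clone 1000:2 from 250:3 stood somewhat apart from its replicates. Its counts differed from theirs by 46.5 and 37.3 times the counting variance, while those 2 libraries differed from each other by 7.44 times.

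**Figure D1:**
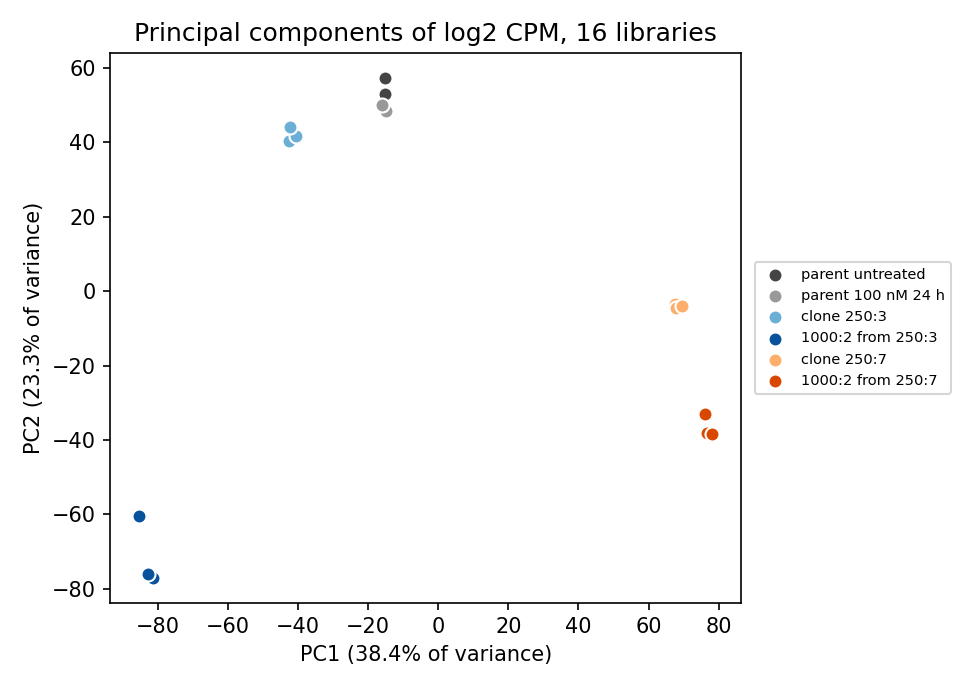
Principal component analysis of log2 CPM, with 1 point per library, coloured by group. The axes are components 1 (38.4% of variance) and 2 (23.3%). The 250:7 lineage lies at 67.7 to 78.2 on component 1, and the 250:3 lineage at -85.3 to -40.5.

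Wee1 phosphorylates and restrains CDK1, the kinase that drives entry into mitosis, so the drug's target and its neighbours in that pathway were examined in every comparison. WEE1 (ENSG00000166483, chromosome 11, 9573681 to 9593457, GRCh38) lay at 28.2 CPM in both parent groups. CDK1 (ENSG00000170312, chromosome 10, 60778331 to 60794852) lay at 175 CPM in the untreated parent. CCNB1, its cyclin partner (ENSG00000134057, chromosome 5, 69167010 to 69178245), lay at 330 CPM. CCNE1, the cyclin of S phase entry (ENSG00000105173, chromosome 19, 29811898 to 29824308), lay at 12.5 CPM. CDC25A, a phosphatase that removes the mark set by Wee1 (ENSG00000164045, chromosome 3, 48157146 to 48188402), lay at 73.8 CPM. PKMYT1, the kinase related to Wee1 (ENSG00000127564, chromosome 16, 2968024 to 2980539), lay at 39.0 CPM. The checkpoint kinase gene CHEK1 (ENSG00000149554, chromosome 11, 125625136 to 125676255) lay at 34.1 CPM. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 (ENSG00000124762, chromosome 6, 36676460 to 36687339), lay at 1.95 CPM. The drug efflux pump genes ABCB1 (ENSG00000085563, chromosome 7, 87503633 to 87713323) and ABCG2 (ENSG00000118777, chromosome 4, 88090264 to 88231322) lay at 8.2 and 21.1 CPM.

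The treated and untreated parent were compared to find the acute response of drug-naive cells, with 2 libraries against 2. INHBE, an activin subunit gene, went from 0.301 to 6.24 CPM (4.36 ± 0.39, adjusted p = 2.14e-06). NUPR1, a stress-induced transcription regulator, went from 0.943 to 17.4 CPM (4.2 ± 0.40). CHAC1, which encodes a glutathione-degrading enzyme, rose by 3.46 ± 0.20, and ASNS, the asparagine synthetase gene, rose from 29.3 to 180 CPM (2.62 ± 0.15), both at an adjusted p of 4.19e-08. PAPPA2, which encodes a protease of insulin-like growth factor binding proteins, rose from 5.42 to 70.6 CPM, while SLC6A9, OSCAR and TRAF1 also stood among the 8 largest rises at 3.71, 2.51 and 2.51. The largest falls were smaller. MEST fell by 1.66 ± 0.21, STARD4, a sterol transport gene, fell by 1.29, and IGFBP3 fell from 6.29 to 2.63 CPM. PTGER2, a prostaglandin receptor gene, fell by 1.20 ± 0.09.

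Of the 10 genes listed above, PKMYT1 fell from 39.0 to 27.0 CPM (-0.53 ± 0.10, adjusted p = 0.00198). WEE1 changed by 0.00 ± 0.09 (adjusted p = 0.996), CDK1 by -0.11 (adjusted p = 0.48), CCNB1 by -0.03 (adjusted p = 0.907), CHEK1 by -0.23 (adjusted p = 0.333) and ABCB1 by -0.36 (adjusted p = 0.243), none of which passed the test. CDKN1A (0.82 ± 0.18), CDC25A (-0.56) and ABCG2 (-0.56) passed it with all libraries, at adjusted p of 0.00675, 0.0309 and 0.0177. Leaving out 1 library, when 1 arm held a single library, turned no direction of these 3 but lost calls of each. CDKN1A was lost without untreated library 2 (adjusted p = 0.0567), untreated library 10 (0.0575) or treated library 1 (0.07). CDC25A and ABCG2 were lost whichever library was left out, at adjusted p of 0.0585 to 0.2 and 0.0591 to 0.135. CCNE1 changed by -0.59 (adjusted p = 0.0756), and was called without a filter on low counts (adjusted p = 0.00199), by DESeq2 (0.032) and in a fit of the 4 parent libraries alone (0.0152).

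Unfolded protein response and ATF4 target genes rose as a group in the treated parent. Over all genes 21 of 31 members rose and 6 fell, against 21 and 7 adjusted over the list alone, with a median of 1.04 (camera adjusted p = 2.47e-61, and 0.000351 with an estimated correlation). SESN2, a stress-induced inhibitor of mTORC1 signalling, rose from 11.6 to 65.6 CPM (2.50 ± 0.11), and PHGDH, the first enzyme of serine synthesis, rose from 112 to 350 CPM. Of 24 NRF2 targets 13 rose and 0 fell, and 17 rose adjusted over the list alone (camera adjusted p = 6.48e-23, and 0.00957 with an estimated correlation). They included the cystine transporter gene SLC7A11 (26.4 to 121 CPM), the ferritin genes FTH1 and FTL (0.86 and 0.89) and NQO1 (0.83). NF-kB targets rose in 13 of 32 members and fell in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 2.32e-12, and 0.000351 with an estimated correlation). Among them IL1B, the interleukin-1 beta gene, went from 18.0 to 43.8 CPM, and BIRC3 rose by 1.11 ± 0.10. Of 28 p53 targets 11 rose and 0 fell (11 and 1 adjusted over the list alone; camera adjusted p = 6.08e-10, and 0.00138 with an estimated correlation), led by GDF15 (2.40 ± 0.26), GADD45A (0.92) and PMAIP1 (0.89).

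Sterol and replication genes fell in the same comparison. Of 28 cholesterol synthesis and SREBP targets 19 fell and 0 rose, and 22 fell adjusted over the list alone (median -0.46, camera adjusted p = 7.05e-20, but adjusted p = 0.0935 with an estimated correlation). SC5D, a gene of cholesterol synthesis, fell by 0.76. DNA replication genes fell in 19 of 45 members and rose in 1 (33 and 1 adjusted over the list alone; camera adjusted p = 2.08e-14, but adjusted p = 0.309 with an estimated correlation), as RRM2, a ribonucleotide reductase subunit gene, fell from 225 to 143 CPM. Homologous recombination and fork protection genes fell in 14 of 34 members and rose in 0 (15 and 0 adjusted over the list alone; camera adjusted p = 9.24e-09, but adjusted p = 0.099 with an estimated correlation), among them SLFN11 (-0.70 ± 0.08) and FANCA (-0.57). Of the G2/M regulators 7 of 31 fell, 9 adjusted over the list alone, and 0 rose (camera adjusted p = 8.12e-05, but adjusted p = 0.425 with an estimated correlation). The list of 30 replication-dependent histones was not called (camera adjusted p = 0.884).

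In all, 998 genes rose and 1034 fell, of which 235 changed at least 2-fold, and 4882 had an unadjusted p under 0.05. The count of 2032 fell to 803 without untreated library 2 (395 rose, 408 fell), 1160 without untreated library 10 (479 rose, 681 fell), 1003 without treated library 1 (625 rose, 378 fell) and 1115 without treated library 9 (426 rose, 689 fell), so that the balance of rises and falls depended on single libraries. With 2 libraries per group, a lone remaining library was assumed to vary like the other groups.

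**Figure D2:**
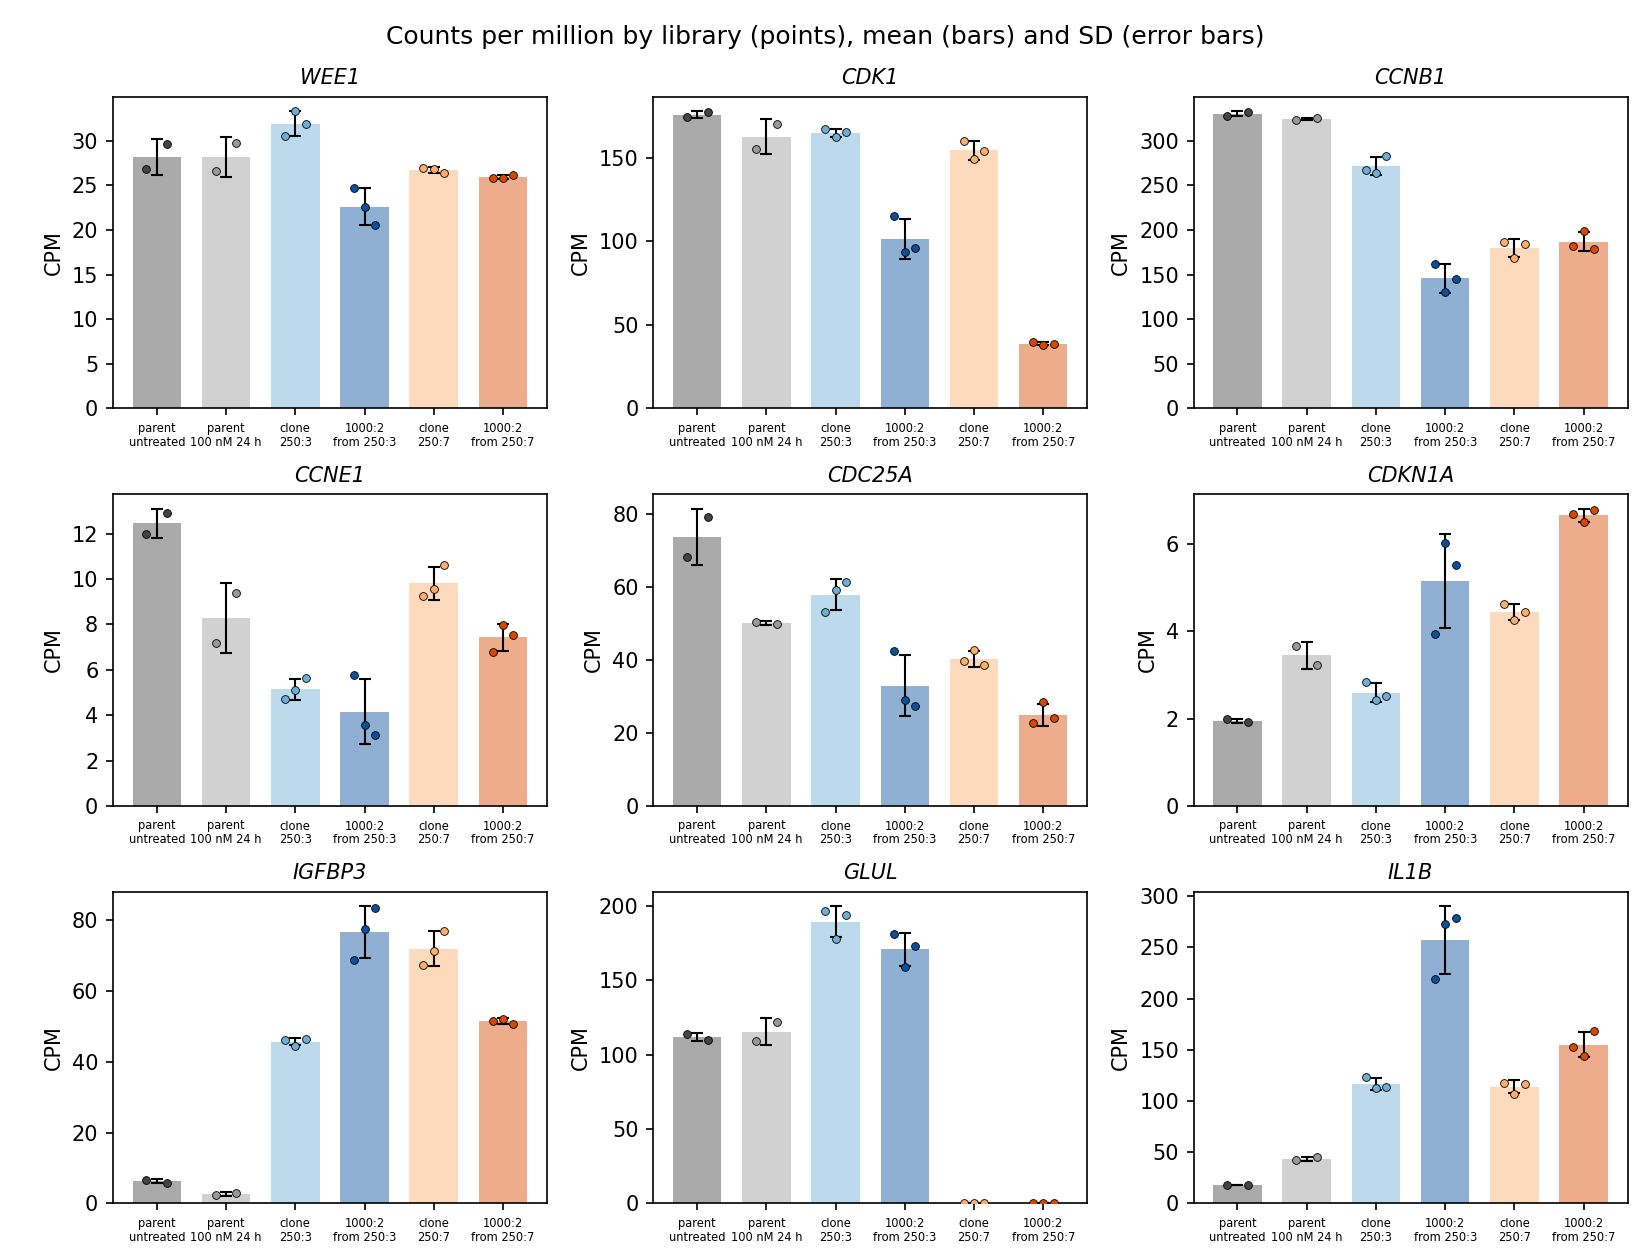
CPM of 9 genes in the 6 groups, with bars for the mean, error bars for the SD and points for single libraries (n = 2 for each parent group, n = 3 for each clone). CDK1 was lowest in clone 1000:2 from 250:7, at 38.7 CPM, and IL1B highest in clone 1000:2 from 250:3, at 257 CPM.

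Clone 250:3 was compared with the untreated parent to find what distinguished the first of the resistant clones, with 3 libraries against 2. IGFBP1, which encodes a binding protein of insulin-like growth factors, rose from 0.632 to 11.9 CPM (4.23 ± 0.20, adjusted p = 9.04e-11). PTK7, a pseudokinase receptor gene, rose from 2.20 to 18.1 CPM, and CD200 from 0.592 to 4.97 CPM. TENM2, a teneurin gene, fell from 42.4 to 0.0181 CPM, a ratio of 2410 (95% interval 824 to 11700). NCAM2, a neural cell adhesion gene, and SORCS3, a sorting receptor gene, fell from 15.6 and 14.9 CPM to 0.00656 CPM each, ratios of 2650 (476 to 105000) and 2530 (454 to 99900). ZNF518B and PTPRD had no counts in the clone and were at least 85-fold and at least 40-fold lower. THY1, a cell surface glycoprotein gene also used as a fibroblast marker, fell from 15 to 0.0275 CPM (-8.87 ± 0.29).

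In clone 250:3, CCNE1 fell from 12.5 to 5.15 CPM (-1.28 ± 0.18, adjusted p = 4.83e-05) and CCNB1 from 330 to 271 CPM (-0.28 ± 0.08, adjusted p = 0.0111), the latter lost without untreated library 10 (adjusted p = 0.0619). ABCG2 passed with -0.45 (adjusted p = 0.0144) and was lost without untreated library 2 (0.074) or 10 (0.0615). WEE1 (0.18), PKMYT1 (-0.14), CDK1 (-0.09), CDC25A (-0.35), CHEK1 (-0.12), CDKN1A (0.41) and ABCB1 (-0.42) did not pass, at adjusted p of 0.0673 to 0.544. ABCB1 was called without untreated library 10 (-0.65, adjusted p = 0.0208) or without clone library 11 (-0.60, adjusted p = 0.00894), and CDC25A in the fit of these groups alone (adjusted p = 0.0081).

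Of 32 NF-kB targets 11 rose and 4 fell in clone 250:3, and 12 and 4 adjusted over the list alone (camera adjusted p = 0.0029, and 0.0462 with an estimated correlation). IL1B rose from 18.0 to 117 CPM (2.70 ± 0.10) and PTGS2, the inducible cyclooxygenase gene, rose from 13.5 to 38.3 CPM, whereas IL24 fell by 2.39. Cancer-testis antigens fell in 9 of 18 measured members and rose in 1, with the same counts adjusted over the list alone (camera adjusted p = 2.27e-06, and 0.00544 with an estimated correlation). MAGEC1 fell from 14.5 to 0.32 CPM while its relative MAGEA6 rose from 9.71 to 45.4 CPM, values that depend on how reads were divided within the family. Hypoxia and glycolysis genes fell in 15 of 33 members and rose in 1, also adjusted over the list alone (camera adjusted p = 8.65e-05, and 0.031 with an estimated correlation), with GPI from 290 to 169 CPM and SLC2A1, the GLUT1 glucose transporter gene, from 158 to 104 CPM. MAPK output genes rose in 14 of 24 members and fell in 3 (14 and 4 adjusted over the list alone; camera adjusted p = 9.98e-05, but adjusted p = 0.179 with an estimated correlation), for example IER3 from 39.0 to 78.5 CPM. SREBP targets fell in 13 of 28 and rose in 2 (14 and 2 adjusted over the list alone; camera adjusted p = 2.57e-05, but adjusted p = 0.816 with an estimated correlation). FADS2, a fatty acid desaturase gene, fell from 53.3 to 17.9 CPM.

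In clone 250:3, 2812 genes rose and 2844 fell, 1211 of them at least 2-fold. The clones had been kept in drug and the untreated parent had not, so drug exposure and clonal difference cannot be separated in any comparison of a clone with the untreated parent. With the treated parent as reference PKMYT1 turned to 0.39, ABCG2 to 0.12 and PAPPA2 to -1.33 in clone 250:3, and SLC2A1 was no longer called (-0.11, adjusted p = 0.303).

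Clone 250:7 was compared with the parent in the same way, 3 libraries against 2. CCL2, a monocyte chemokine gene, rose from 0.0402 to 10.0 CPM (7.88 ± 0.30). PTPRN2, a receptor phosphatase gene of secretory granules, rose from 1.32 to 164 CPM (6.96 ± 0.12, adjusted p = 1.1e-16), and CHRNA1, the muscle acetylcholine receptor subunit gene, rose from 3.85 to 276 CPM. MROH2B had no counts in the parent and was at least 105-fold higher. GLUL, the glutamine synthetase gene (ENSG00000135821, chromosome 1, 182381704 to 182392206), fell from 112 to 0.0136 CPM, a ratio of 8690 (2400 to 71700). CHRDL1, a secreted antagonist of bone morphogenetic proteins, fell from 143 to 0.104 CPM (-10.39 ± 0.18), and IL13RA2, a decoy receptor gene for interleukin-13, from 77.4 to 0.0549 CPM (-10.47 ± 0.23). MAGEH1, MAGEE1 and LRCH2 had no counts in the clone and were at least 121-fold, at least 104-fold and at least 85-fold lower.

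CCNB1 fell from 330 to 180 CPM in clone 250:7 (-0.87 ± 0.08, adjusted p = 9.64e-08), CDC25A from 73.8 to 40.4 CPM (-0.87 ± 0.14, adjusted p = 7.83e-05) and PKMYT1 from 39.0 to 24.5 CPM (-0.67 ± 0.09, adjusted p = 9.18e-06). CDKN1A rose from 1.95 to 4.44 CPM (1.19 ± 0.16) and ABCB1 from 8.2 to 15.7 CPM (0.94 ± 0.16, adjusted p = 0.000144). WEE1 (-0.08, adjusted p = 0.472) and CCNE1 (-0.35, adjusted p = 0.136) did not pass, although CCNE1 was called in a fit of these groups alone (adjusted p = 0.00836). CHEK1 (-0.35) and ABCG2 (0.36) passed with all libraries, at adjusted p of 0.0298 and 0.0323. CHEK1 was lost without untreated library 10 (0.155) or clone library 13 (0.0716). ABCG2 was lost whichever library was left out (0.0531 to 0.173). CDK1 at -0.19 (adjusted p = 0.0568) did not pass, but was called at -0.21 with RLE size factors (adjusted p = 0.0397) and at -0.24 without clone library 5 (adjusted p = 0.031).

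Proliferation genes fell in clone 250:7. Of 31 G2/M regulators 23 fell and 2 rose, and 25 and 2 adjusted over the list alone (median -0.42, camera adjusted p = 3.86e-07, but adjusted p = 0.458 with an estimated correlation), with CCNA2, the cyclin A2 gene, from 99.4 to 30.3 CPM. DNA replication genes fell in 32 of 45 and rose in 1 (34 and 1 adjusted over the list alone; camera adjusted p = 3.86e-07, but adjusted p = 0.537 with an estimated correlation), with MCM2, a subunit gene of the replicative helicase, from 261 to 133 CPM. Replication-dependent histones fell in 23 of 30 (23 adjusted over the list alone) and rose in 0 (median -0.72, camera adjusted p = 9.02e-05, but adjusted p = 0.552 with an estimated correlation). Cancer-testis antigens fell in 10 of 18 and rose in 2 (11 and 3 adjusted over the list alone; camera adjusted p = 9.02e-05, and 0.0262 with an estimated correlation), MAGEA6 at -3.09 and MAGEA11 at 3.51. Collagens and matrix genes rose in 19 of 38 and fell in 6, also adjusted over the list alone (camera adjusted p = 0.000127, but adjusted p = 0.537 with an estimated correlation). VCAN, the proteoglycan versican gene, rose from 15.5 to 70.4 CPM and FBN1, the fibrillin-1 gene, from 130 to 373 CPM. MMP1, the interstitial collagenase gene, rose from 13600 to 35400 CPM and thus took 3.50% ± 0.032 of all counts (SD, n = 3) against 1.38% ± 0.085 in the untreated parent (n = 2). Unfolded protein response genes rose in 17 of 31 and fell in 4 (18 and 4 adjusted over the list alone; camera adjusted p = 0.000368, but adjusted p = 0.458 with an estimated correlation), with ASNS at 132 CPM.

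For clone 250:7, 4291 genes rose and 4443 fell, 2421 of them at least 2-fold. With the treated parent as reference PAPPA2 (-1.16), CHAC1 (-0.44), ASNS (-0.45) and SESN2 (-1.33) turned to falls, and CDKN1A (0.36, adjusted p = 0.0701), PKMYT1 (-0.14, adjusted p = 0.237) and CDC25A (-0.31, adjusted p = 0.091) were no longer called.

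Clone 1000:2 from 250:3 was compared with the parent (3 libraries against 2) and with its progenitor 250:3 (3 against 3). The latter comparison is called the step to 1000 nM. In the steps of both lineages the dose in the medium and the clone differed together, so their effects cannot be separated there either. CD53, a tetraspanin gene of leukocytes, had no counts in the parent and lay at 12.6 CPM, at least 206-fold higher than in the parent and at least 237-fold higher than in the progenitor. MGAM, the maltase-glucoamylase gene, rose from 0.302 CPM in the parent and 0.242 CPM in the progenitor to 407 CPM (10.39 ± 0.38 and 10.63 ± 0.32), and OR9A4 and CLEC5A, which lie within the span of MGAM on chromosome 7, were among the largest rises against the parent. Their counts are uncertain because of that overlap. HLA-DRA, a class II antigen presentation gene, rose from 0.0228 CPM in the progenitor to 38.3 CPM (10.52 ± 0.42). THY1 returned from 0.0275 CPM in the progenitor to 86.7 CPM (11.40 ± 0.25). UBQLN2, which encodes a ubiquilin of protein degradation (ENSG00000188021, chromosome X, 56563639 to 56567868), fell to 1 count over 3 libraries, a ratio of 1780 (320 to 70400) to the parent and 1610 (290 to 63700) to the progenitor. ZXDB and ZXDA, zinc finger genes on the same chromosome, had no counts in the clone and were at least 117-fold and at least 68-fold lower than in the progenitor.

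In clone 1000:2 from 250:3, CCNB1 fell to 146 CPM (-1.18 ± 0.08 against the parent and -0.89 ± 0.07 against the progenitor, adjusted p = 1.65e-09 and 1.58e-08). CDK1 fell to 101 CPM (-0.79 ± 0.07 and -0.70 ± 0.07, adjusted p = 1.22e-07 and 1.69e-07) and CDC25A to 33.0 CPM (-1.16 ± 0.14 and -0.81 ± 0.13). CDKN1A rose to 5.15 CPM (1.40 ± 0.16 and 0.99 ± 0.14, adjusted p = 1.68e-06 and 1.25e-05). WEE1 fell from 31.9 CPM in the progenitor to 22.7 CPM (-0.49 ± 0.07, adjusted p = 1.6e-05). Against the parent WEE1 fell by 0.32 ± 0.08 (adjusted p = 0.00277), a call lost without untreated library 10 (-0.25, adjusted p = 0.0584). PKMYT1 (-0.50 and -0.36) and ABCG2 (-0.97 and -0.52) fell in both. CCNE1 lay 1.59 ± 0.18 below the parent on the log2 scale and did not pass against the progenitor (-0.31, adjusted p = 0.157). Without library 6 it was called there (-0.63, adjusted p = 0.00111), as was CHEK1 (-0.36, against -0.19 with all libraries, adjusted p = 0.165). ABCB1 did not pass against the progenitor (-0.12, adjusted p = 0.547). ABCB1 against the parent (-0.54, adjusted p = 0.0109) was lost without untreated library 2 (-0.29, adjusted p = 0.255), and CHEK1 (-0.31, adjusted p = 0.0443) without either untreated library (0.059 and 0.229) or clone library 7 (0.137) or 14 (0.133).

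NF-kB targets had the smallest camera p of the 33 lists in both comparisons of this clone. Against the parent 24 of 32 rose and 4 fell, and 25 and 5 adjusted over the list alone, with a median of 1.28 (camera adjusted p = 5.05e-18, and 6.8e-05 with an estimated correlation). Against the progenitor 25 rose and 4 fell, and 26 and 4 adjusted over the list alone (median 1.26, camera adjusted p = 3.28e-16, and 8.78e-05 with an estimated correlation). IL1B rose from 18.0 CPM in the parent to 257 CPM (3.83 ± 0.11), BIRC3, an inhibitor of apoptosis gene, from 6.73 to 55.8 CPM, and TNFAIP3, which encodes the NF-kB inhibitor A20, from 12.5 to 104 CPM. VCAM1, an adhesion gene of the same list, fell from 7.09 to 0.0888 CPM (-6.26 ± 0.25). Interferon-stimulated genes rose in 26 of 37 members against the progenitor and fell in 3 (27 and 3 adjusted over the list alone; camera adjusted p = 3.49e-06, but adjusted p = 0.152 with an estimated correlation), among them UBE2L6 (3.33 ± 0.16) and STAT2 (38.9 to 85.3 CPM), whereas the RNA sensor gene DDX58 fell by 1.48. Antigen presentation genes rose in 17 of 25 and fell in 3, also adjusted over the list alone (camera adjusted p = 9.24e-12, but adjusted p = 0.152 with an estimated correlation). HLA-DPA1 rose from 0.783 to 49.9 CPM and HLA-DMA by 3.15. Of the immune cell markers, PTPRC, a general leukocyte marker, was not called against the parent (0.04), while the macrophage-expressed CD68 (35.4 to 66.2 CPM) and LYZ (0.271 to 2.13 CPM) rose. CD68 was thus already expressed in the untreated parent line. That list of 11 measured genes was not called (3 rose, camera adjusted p = 0.194). Markers of other ovarian cancer lineages were not called as a list either. Against the parent 5 of 11 rose and 0 fell, also adjusted over the list alone (median 0.94, camera adjusted p = 0.192), and against the progenitor 6 rose and 1 fell, and 7 and 1 adjusted over the list alone (median 1.40, camera adjusted p = 0.0721). The list was called against the progenitor without clone library 6 (camera adjusted p = 0.0446).

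Replication-dependent histones fell in 30 of 30 members against the progenitor and against the parent, with the same counts adjusted over the list alone. The median was -1.37 in each (camera adjusted p = 6.63e-15 and 5.63e-15, but adjusted p = 0.376 and 0.47 with an estimated correlation). HIST1H1A fell from 17.7 CPM in the parent to 2.89 CPM (-2.62 ± 0.17). Against the parent G2/M regulators fell in 24 of 31 and rose in 0 (25 and 0 adjusted over the list alone; camera adjusted p = 2.32e-10, but adjusted p = 0.297 with an estimated correlation), with CCNE2 from 38.1 to 10.3 CPM. DNA replication genes fell in 34 of 45 and rose in 4 (34 and 5 adjusted over the list alone; camera adjusted p = 1.62e-07, but adjusted p = 0.493 with an estimated correlation), and PCNA, the sliding clamp gene, fell from 215 to 72.1 CPM. Library 6 showed less of these falls than libraries 7 and 14. Its median distance from the untreated parent was -0.90 for histones against -1.75 and -1.71, -0.48 for G2/M regulators against -0.67 in each, and -0.29 for replication genes against -0.57 and -0.58. Without it the histone median against the parent was -1.74. MYC-regulated ribosome biogenesis genes fell in 27 of 30 against the progenitor and rose in 0, also adjusted over the list alone (camera adjusted p = 1.72e-12, but adjusted p = 0.339 with an estimated correlation), with BOP1 from 193 to 61.2 CPM. MAPK output genes fell in 16 of 24 and rose in 3 (17 and 3 adjusted over the list alone; camera adjusted p = 1.14e-05, but adjusted p = 0.152 with an estimated correlation), and EREG, an EGF receptor ligand gene, fell from 91.4 to 22.9 CPM. In this clone protein-coding genes of chromosome 8 lay at -0.68 against the parent and -0.56 against the progenitor. Both are distances from the median over all chromosomes, among genes with a mean of at least 1 CPM. Of these genes 60.3% and 57% were called as falls, and 23.5% and 29.2% as rises. Whether position on a shifted chromosome added to the falls of single list members, such as CCNE2 and BOP1, was not tested.

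Against the parent 5466 genes rose and 5127 fell in clone 1000:2 from 250:3, with 3644 at least 2-fold. Against the progenitor 5496 rose and 5021 fell, with 3231 at least 2-fold. Without library 6 these totals of 10593 and 10517 were 10853 and 10740, and 17 lists instead of 11 were called against the progenitor. With the treated parent as reference PKMYT1 was 0.03 and PAPPA2 turned from 2.09 to -1.61.

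**Figure D3:**
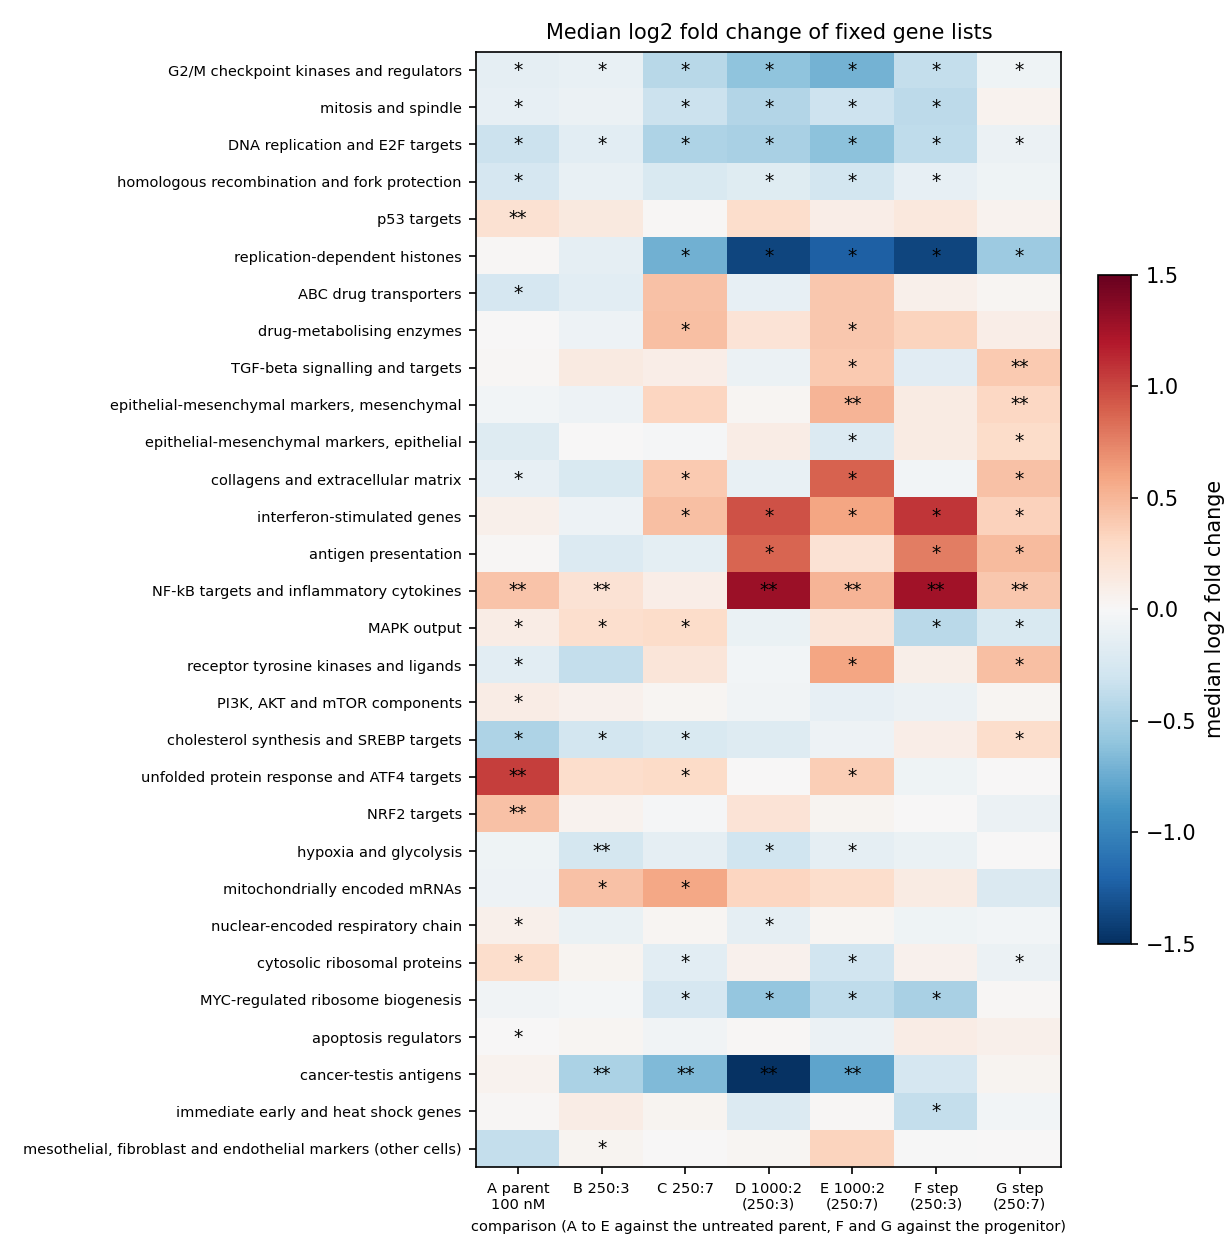
Median log2 fold change of each gene list (vertical axis) in 7 comparisons (horizontal axis: treated parent and 4 clones against the untreated parent, and both 1000 nM clones against their progenitors). One star marks a camera call at a preset correlation and 2 stars a call that also held with an estimated correlation; NF-kB targets in clone 1000:2 from 250:3 had medians of 1.28 and 1.26.

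Clone 1000:2 from 250:7 was set against the parent and its progenitor 250:7 in the same way. POSTN, the matrix protein periostin gene, rose from 0.0666 CPM in the progenitor to 29.1 CPM (8.75 ± 0.41), and THBS2, a matrix glycoprotein gene, by 6.67 ± 0.32. SERINC2 (ENSG00000168528, chromosome 1, 31409565 to 31434680) rose from 8.05 to 386 CPM (5.58 ± 0.11, adjusted p = 1.15e-15). CCL2, at 10.0 CPM in the progenitor, rose further to 42.1 CPM, and was 9.95 ± 0.28 above the parent. INA, a neuronal filament gene, had no counts and was at least 145-fold lower than in the progenitor. TLR4, the lipopolysaccharide receptor gene, fell from 17.4 to 0.0401 CPM (-8.68 ± 0.31), RARB, a retinoic acid receptor gene, from 12 to 0.0522 CPM, and S1PR3 from 33.1 to 0.172 CPM. GLUL lay at 0.31 CPM, against 112 CPM in the parent (-8.48 ± 0.14).

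CDK1 fell from 154 CPM in the progenitor to 38.7 CPM (-1.99 ± 0.07, adjusted p = 2.57e-12) and lay 2.18 ± 0.08 below the parent on the log2 scale (adjusted p = 4.94e-13). All 17 protein-coding neighbours of CDK1 within 5 Mb with a mean of at least 1 CPM, a set chosen after its values were seen, fell as well, with a median of -1.66 and a range of -2.21 to -0.53. Of the 4 less expressed protein-coding genes there, EGR2 (-2.85, adjusted p = 0.0165) and TMEM26 (-1.25, adjusted p = 0.0345) fell, while FAM13C (-0.95, adjusted p = 0.098) and MRLN (-0.60, adjusted p = 0.298) were not called. Against the progenitor CDC25A fell by 0.69 ± 0.13 (adjusted p = 0.00057) and CDKN1A rose by 0.58 ± 0.13 (adjusted p = 0.00293). WEE1 (-0.04, adjusted p = 0.707), PKMYT1 (-0.04, adjusted p = 0.78), CCNB1 (0.05, adjusted p = 0.648), CHEK1 (-0.19, adjusted p = 0.218), ABCB1 (0.19, adjusted p = 0.364), ABCG2 (0.22, adjusted p = 0.165) and CCNE1 (-0.40, adjusted p = 0.0862) did not pass. ABCG2 was called without clone library 15 (0.39, adjusted p = 0.00226), and CCNE1 without a filter on low counts (adjusted p = 0.00865). Against the parent CCNB1 fell to 187 CPM (-0.82 ± 0.08, adjusted p = 1.22e-07), CDC25A to 25.0 CPM (-1.56 ± 0.14), CCNE1 to 7.42 CPM (-0.75 ± 0.18) and PKMYT1 to 23.8 CPM (-0.71 ± 0.09). CHEK1 fell by 0.54 ± 0.12, while CDKN1A (1.77 ± 0.16, adjusted p = 1.08e-07), ABCB1 (1.13 ± 0.16, adjusted p = 1.67e-05) and ABCG2 (0.58 ± 0.13, adjusted p = 0.00111) rose, and WEE1 did not pass (-0.12, adjusted p = 0.222).

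**Figure D4:**
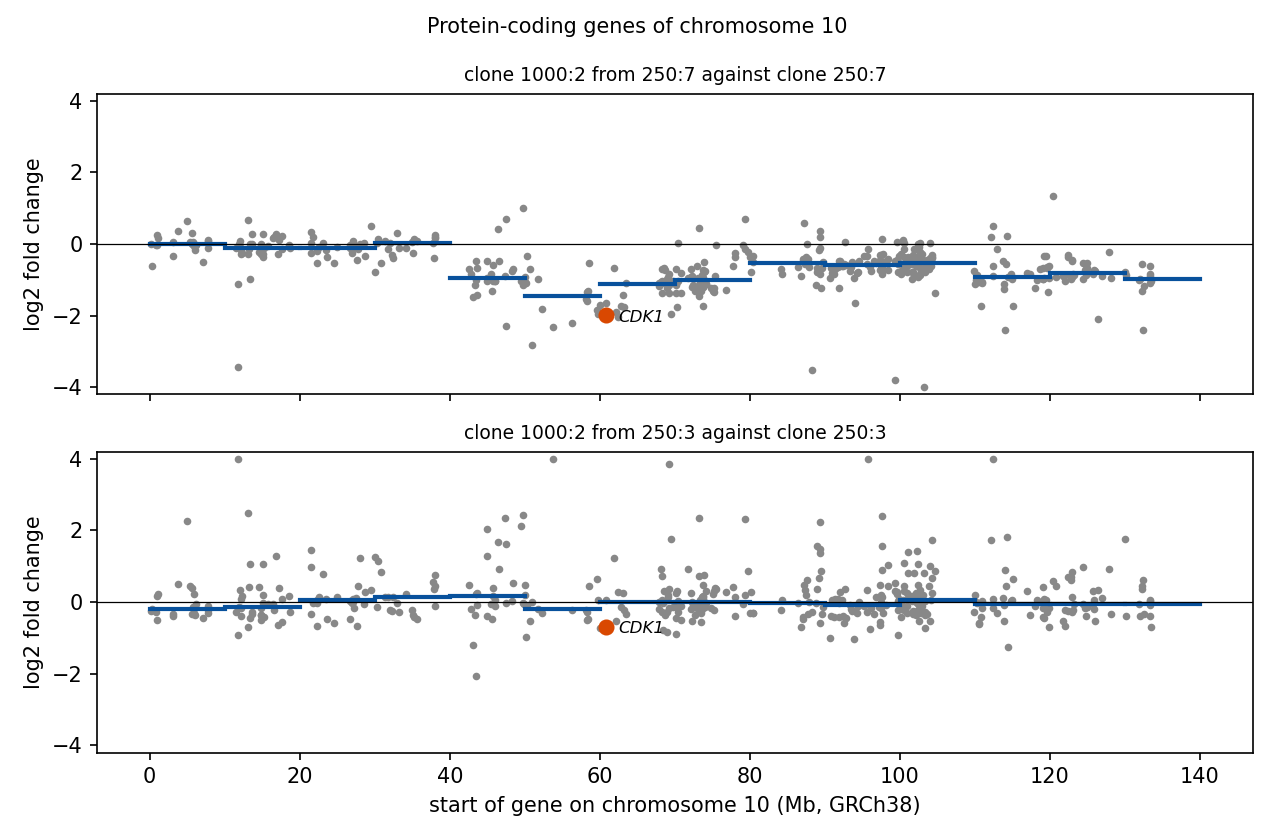
Log2 fold change of protein-coding genes with a mean of at least 1 CPM along chromosome 10 (position in Mb, GRCh38) in both 1000 nM clones against their progenitors, with 1 point per gene and values beyond 4 drawn at 4. The 17 of them within 5 Mb of CDK1 had a median of -1.66 in the 250:7 lineage and -0.22 in the 250:3 lineage.

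Matrix genes rose with the step to 1000 nM in the 250:7 lineage. Of 38 collagens and matrix genes 25 rose and 2 fell against the progenitor, also adjusted over the list alone (median 0.44, camera adjusted p = 4.49e-17, but adjusted p = 0.106 with an estimated correlation). COL12A1 rose from 187 to 480 CPM and COL4A1, a basement membrane collagen gene, from 154 to 386 CPM. Mesenchymal markers rose in 10 of 19 and fell in 2 (11 and 2 adjusted over the list alone; camera adjusted p = 6.72e-06, and 0.00746 with an estimated correlation), with SPARC from 276 to 787 CPM and LOX, the collagen cross-linking oxidase gene, from 310 to 827 CPM. TGF-beta pathway genes rose in 18 of 34 and fell in 4 (19 and 5 adjusted over the list alone; camera adjusted p = 0.000224, and 0.0212 with an estimated correlation), and THBS1 rose from 424 to 1150 CPM. NF-kB targets rose in 17 of 32 and fell in 5 (18 and 5 adjusted over the list alone; camera adjusted p = 1.97e-05, and 0.00746 with an estimated correlation), TNFAIP3 at 1.47 ± 0.08 and CXCL1 at 1.63 ± 0.10, while PTGS2 fell by 1.99 ± 0.12. Histones fell in 18 of 30 and rose in 0 (20 and 0 adjusted over the list alone; camera adjusted p = 0.000146, but adjusted p = 0.792 with an estimated correlation). The G2/M list had 7 members that fell and 2 that rose of 31, also adjusted over the list alone, and its camera adjusted p of 0.0269 became 0.0712 without clone library 16 (adjusted p = 0.792 with an estimated correlation).

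Against the parent, the same clone had matrix genes higher in 24 of 38 members and lower in 4, also adjusted over the list alone (median 0.88, camera adjusted p = 1.58e-16, but adjusted p = 0.0957 with an estimated correlation). LAMA4, a laminin chain gene, rose from 217 to 1220 CPM, and of the mesenchymal markers (12 of 19 rose, 4 fell, also adjusted over the list alone; camera adjusted p = 4.48e-05, and 0.0235 with an estimated correlation) CDH2, the N-cadherin gene, rose from 129 to 454 CPM. NF-kB targets rose in 17 of 32 and fell in 8, also adjusted over the list alone (camera adjusted p = 0.000627, and 0.0299 with an estimated correlation), with VCAM1 from 7.09 to 136 CPM. Histones fell in 29 of 30 members (30 adjusted over the list alone) and rose in 0 (median -1.23, camera adjusted p = 2.71e-09, but adjusted p = 0.471 with an estimated correlation). G2/M regulators fell in 26 of 31 and rose in 1, also adjusted over the list alone (camera adjusted p = 1.4e-09, but adjusted p = 0.222 with an estimated correlation). DNA replication genes fell in 34 of 45 and rose in 1 (37 and 1 adjusted over the list alone; camera adjusted p = 1.4e-09, but adjusted p = 0.414 with an estimated correlation). Interferon-stimulated genes rose in 21 of 37 and fell in 2 (22 and 3 adjusted over the list alone; camera adjusted p = 4.48e-05, but adjusted p = 0.156 with an estimated correlation), with SAMD9L from 3.30 to 55.9 CPM. Of 13 measured mesothelial, fibroblast and endothelial markers, 4 rose and 1 fell, also adjusted over the list alone (median 0.33, camera adjusted p = 0.829, not called). The 1 that fell, the endothelial cadherin gene CDH5, lay at 117 CPM in the parent itself and at 10.0 CPM in this clone.

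In clone 1000:2 from 250:7, 5122 genes rose and 4977 fell against the parent, with 3286 at least 2-fold, and 3154 rose and 2860 fell against the progenitor, with 1279 at least 2-fold. With the treated parent as reference PAPPA2 (-1.09), ASNS (-0.97) and SESN2 (-1.27) turned to falls, and CCNE1 (-0.16, adjusted p = 0.528) and PKMYT1 (-0.18, adjusted p = 0.113) were no longer called.

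Genes called in the same direction in all 4 clones against the parent numbered 607 that rose and 656 that fell, 103 and 104 of them at least 2-fold in each clone. These comparisons share the untreated libraries, and each 1000 nM clone derives from a 250 nM clone, so the lists are not independent, and no number expected by chance was computed for this overlap. IGFBP3 (ENSG00000146674, chromosome 7, 45912245 to 45921874), which encodes the main circulating binding protein of insulin-like growth factors, rose from 6.29 CPM to 45.7 in clone 250:3, 76.6 in its 1000 nM clone, 72.0 in clone 250:7 and 51.5 in its 1000 nM clone. It had fallen to 2.63 CPM in the treated parent. IL1B (ENSG00000125538, chromosome 2, 112829751 to 112836903) rose from 18.0 CPM to 117, 257, 114 and 155 CPM in the same order. CPT1A, the gene of the carnitine shuttle that admits fatty acids to mitochondria, rose from 0.942 CPM to 3.19, 8.01, 10.8 and 14 CPM, and BOK, a BCL2 family gene, from 1.26 CPM to 4.37, 14.1, 7.61 and 4.54 CPM. SPANXB1, a cancer-testis gene with near-identical copies, fell from 52.7 CPM to 0.178, 0, 0.0396 and 0.0734 CPM. DSG2, a desmosomal cadherin gene, fell from 6.13 CPM to 0.157, 0.0827, 0.0719 and 0.0791 CPM, and ADAMTS2, a procollagen protease gene, from 41.9 CPM to 0.162, 0.321, 1.81 and 0.753 CPM.

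Clones 250:3 and 250:7 shared 1130 genes that rose and 1175 that fell, against 555 and 582 expected of independent lists. Simulated unchanged groups gave 0 and 0, but few calls are expected in such groups at the adjusted threshold, so these values do not measure what the shared controls add. Log2 changes of these clones correlated across genes at r = 0.324 (simulated 0.627), and the covariance was 0.332 against a simulated 0.129. In unchanged groups r is set by the numbers of shared and unshared libraries. Real changes add variance, so real and simulated r cannot be ranked against each other. For the 1000 nM clones the overlaps were 2342 and 2453 against 1289 and 1175 expected, with r = 0.363 (simulated 0.62) and a covariance of 0.578 against 0.128. Genes that rose in the treated parent also rose in clone 250:3 (413 against 129 expected), clone 250:7 (506 against 197) and the 1000 nM clones from 250:3 (564 against 251) and from 250:7 (494 against 235). Both-fell overlaps were 497 against 135, 487 against 211, 622 against 244 and 432 against 237. Correlations with the treated parent, in the same order, were 0.361, 0.343, 0.322 and 0.325 (simulated 0.557 to 0.563). Covariances were 0.224, 0.259, 0.282 and 0.269, against simulated values of 0.128 or 0.129. Each of these pairs shares both untreated libraries, so part of the excess may come from the shared controls. Genes are not independent replicates.

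The steps from 250 to 1000 nM of both lineages shared no library. Of the genes that rose in the 250:3 lineage 1347 also rose in the 250:7 lineage (798 expected), and 1127 fell in both (661 expected; Fisher's exact test, p = 1.84e-119 and 2.12e-98, with genes taken as independent). Opposite calls numbered 616 and 795, against 724 and 729 expected, and the correlation across genes was 0.186. The difference between the steps was tested directly as an interaction and called 8235 genes, 4185 with a higher and 4050 with a lower change in the 250:3 lineage. SYNDIG1, a synaptic protein gene, went from 0 to 15.4 CPM in the 250:3 lineage and from 0.354 to 0.604 CPM in the 250:7 lineage (adjusted p = 8.32e-10). INA went from 0.367 to 0.646 CPM and from 8.44 to 0 CPM (adjusted p = 4.25e-11). BEX1 went from 1.32 to 0.0133 CPM and from 0.156 to 6.91 CPM (adjusted p = 1.36e-11), and IL13RA2 from 54.8 to 0.258 CPM and from 0.0549 to 0.351 CPM (adjusted p = 4.97e-10). NF-kB targets had the larger rise in the 250:3 lineage, with 19 of 32 members higher and 2 lower (20 and 2 adjusted over the list alone; camera adjusted p = 1.5e-05, and 0.0124 with an estimated correlation). TGF-beta pathway genes were higher in the step of the 250:7 lineage (17 of 34, with 6 the other way, and 17 and 7 adjusted over the list alone; camera adjusted p = 0.000107, and 0.0242 with an estimated correlation), as were mesenchymal markers (10 of 19, with 3 the other way, also adjusted over the list alone; camera adjusted p = 0.00094, and 0.0242 with an estimated correlation).

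Clones 250:3 and 250:7, both selected at 250 nM, differed in 10148 genes, 5072 higher and 5076 lower in 250:3, with 2809 at least 2-fold. GLUL lay at 190 CPM in 250:3 and 0.0136 CPM in 250:7, a ratio of 14700 (4070 to 121000), and CHRDL1 at 250 and 0.104 CPM (11.19 ± 0.17). SORCS3 lay at 0.00656 and 182 CPM, NCAM2 at 0.00656 and 138 CPM, and PTPRN2 at 0.0126 and 164 CPM, ratios of 31000 (5560 to 1220000), 23500 (4230 to 930000) and 14000 (3870 to 115000). STAC and DDX53 had no counts in 250:3 and were at least 206-fold and at least 165-fold lower there. Matrix genes were lower in 250:3 in 23 of 38 members and higher in 4 (23 and 5 adjusted over the list alone; camera adjusted p = 1.07e-05), and G2/M regulators were higher in 21 of 31 and lower in 3 (22 and 3 adjusted over the list alone; camera adjusted p = 0.00312), each with an adjusted p = 0.789 with an estimated correlation. At the preset correlation camera called 12 lists between these clones, and 0 with an estimated correlation, where the drug-metabolising enzymes alone had an unadjusted p under 0.05 (0.0211).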

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

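The step from 250 to 1000 nM was measured in both lineages, and an interaction test of that step singled out the results that follow. The tests of a change in CDK1 itself, of the other G2/M regulators, of RNAs without a poly(A) tail, of S phase, and both tests of the X chromosome were chosen only after the result was seen. The test over most of the long arm of chromosome 10 was added once the 5 Mb test had been left undecided, with bounds set after the protein-coding bins were seen. How much spread was allowed for in the 5 Mb test and in the tests of histone position was revised after their values were known, and the chromosome X test was rewritten after a first version had given 4 of 6 genes. No group had the 4 libraries needed for a test of single outlying libraries.

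The interaction called 8235 genes (edgeR's quasi-likelihood test, Benjamini-Hochberg). Of 100 splits of the 12 clone libraries that kept the group sizes, 1, the real one, gave as many, and the highest of the others gave 1667. The other splits mixed libraries of distinct clones within a group, which widens the spread within groups, so fewer calls were to be expected of them. Neither these splits nor those below can decide whether chance divergence between single clones gave the counts. For the step in the 250:3 lineage (10517 genes), the step in the 250:7 lineage (6014) and the 250 nM clones against each other (10148), the real split was 1 of 10 each time, and the highest other split gave 1, 0 and 0 genes at the adjusted threshold. With 10 splits no share can come under 0.05.

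Positive values mean a higher change in the 250:3 lineage. List medians of the difference were -0.14 for G2/M regulators (camera adjusted p = 0.00245), -0.41 for mitosis genes (5.84e-06), -0.87 for histones (1.74e-05), -0.46 for MYC-regulated ribosome biogenesis (7.16e-08) and -0.47 for matrix genes (0.00404), each with an adjusted p of 0.736 or 0.746 with an estimated correlation. They were 0.70 for NF-kB targets (1.5e-05), -0.44 for TGF-beta genes (0.000107) and -0.40 for mesenchymal markers (0.00094), called under both. Chromosome 6, which holds the main histone cluster, itself differed between the lineages by -0.56 relative to the median of all genes (adjusted p = 0.0107 with an estimated correlation). Position was not tested for the histone difference. Interferon-stimulated genes had 0.32 (camera adjusted p = 0.0447, but adjusted p = 0.736 with an estimated correlation), a call lost without library 4 of 250:3 (0.0574), library 14 of its 1000 nM clone (0.0615), library 5 of 250:7 (0.0518) or library 15 of its 1000 nM clone (0.0812). Among single genes the difference was -0.45 for WEE1 (adjusted p = 0.00165), -0.32 for PKMYT1 (0.0318), 1.30 for CDK1 (1.51e-08), -0.95 for CCNB1 (8.7e-07) and -0.74 for ABCG2 (0.00146).

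The genes with the largest differences are given as CPM from progenitor to 1000 nM clone, first in the 250:3 and then in the 250:7 lineage. SLC9A2 went from 0 to 10.8 and from 0.00599 to 0 (adjusted p = 0.00144, but 1 without library 5 of 250:7). INA went from 0.367 to 0.646 and from 8.44 to 0 (4.25e-11), PROSER2 from 0 to 5.55 and from 2.08 to 0.966 (1.33e-09), and SYNDIG1 from 0 to 15.4 and from 0.354 to 0.604 (8.32e-10). CD53 went from 0 to 12.6 and from 0.0263 to 0.0533 (8.98e-05), and BEX1 from 1.32 to 0.0133 and from 0.156 to 6.91 (1.36e-11). ZXDB went from 7.05 to 0 and from 5.89 to 4.89 (1.87e-11), ZXDA from 4.12 to 0 and from 3.85 to 4.2 (3.36e-11), and ARRDC4 from 3.56 to 0 and from 5.75 to 7.09 (3.07e-11). IL13RA2 went from 54.8 to 0.258 and from 0.0549 to 0.351 (4.97e-10).

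CDK1 fell with its neighbours in the 250:7 lineage, where all 17 protein-coding genes within 5 Mb with a mean of at least 1 CPM fell (median -1.66, against -0.22 in the other lineage), and of 4 less expressed ones EGR2 and TMEM26 fell while FAM13C and MRLN were not called. A change confined to CDK1 is argued against, since 11.8% of those 17 neighbours, and EGR2 (-2.85) besides, fell by more than CDK1. These neighbours also made up the pattern, and CDK1 fell by more than most of them. A further fall of CDK1 beyond that of its region was therefore not excluded. A fall with the other G2/M regulators is argued against by their median of -0.06. The 4 genes of other types within 5 Mb had a median of -0.49 with a spread of 1.09 (median absolute deviation), which leaves that test open and lies 0.01 on the side against the explanation by its original bound of -0.5. Between 40 and 130 Mb, 297 of 339 protein-coding genes with a mean of at least 1 CPM fell and 7 rose, and 202 genes of other types, not used in finding the pattern, had a median of -0.57 with a spread of 0.69 (median absolute deviation). A candidate explanation is lower output of much of the long arm at unequal depth (-1.45 to -0.53 in bins of 10 Mb), as after loss of copies, but regional silencing and loss of copies were not told apart, and no DNA measurement was used here.

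Replication-dependent histone mRNAs were lower in both 1000 nM clones than in the parent, with medians of -1.37 and -1.23 (camera adjusted p = 5.63e-15 and 2.71e-09, but adjusted p = 0.47 and 0.471 with an estimated correlation). Position on chromosome 6 is argued against by histone genes on chromosome 1 outside the list, at -0.75 and -1.63 (10 genes), and by 28 other genes at 25 to 30 Mb of chromosome 6, at 0.07 and 0.18. Poorer recovery of RNAs without a poly(A) tail is argued against, for the RNAs covered, by 13 structural RNAs, at 0.12 and 0.09. Classes of small RNA differed, however. The share of counts of snoRNAs went from 1.297% and 0.895% in the untreated parent to 0.438% to 0.57% and 0.698% to 0.803% in these clones. That of snRNAs went the other way, from 2.219% and 2.081% to 2.38% to 2.983% and 2.757% to 3.051%. Fewer cells in S phase, in which these mRNAs accumulate, would go with the DNA replication list, at -0.49 and -0.61. That list was not called with an estimated correlation (camera adjusted p = 0.493 and 0.414). In treated parent libraries 1 and 9, however, the replication list lay at -0.3 and -0.28 and histones at -0.1 and 0.09, so the former can fall without the latter. Fewer cells in S phase remains a hypothesis, because cell cycle phase was not measured. Whether the drug in the medium or the clone sets the histone level stays open, as untested.

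A run of genes on the short arm of chromosome X (56563639 to 57910820) was near 0 in clone 1000:2 from 250:3. Too few reads are argued against for UBQLN2 alone, since its progenitor level would give 1614 counts over the 3 libraries and 1 was seen. UBQLN2 had been named under the rule of a mean count of at least 100 in the higher group. The test was therefore sure to come out this way, and expected counts of the other genes were not computed. Loss of the whole stretch from every cell is argued against as well, because NBDY kept 42.3% and SPIN3 9.12% of the progenitor level, while UBQLN2, SPIN2B, ZXDB and ZXDA kept 1% or less. Loss of part of the stretch and silencing of single genes may each leave such values and were not tested.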

How the results depend on the processing

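Of the alternatives in this part, the count without genes of shifted chromosomes was chosen only after the result was seen. No paired analysis was possible because no groups share library numbers. Every count of changed genes stayed within 1.5 times its value under RLE size factors, no filter, DESeq2, limma on variance-stabilised values, a fit of only the libraries compared, transcript sums with a length offset, and the library number covariate. So did the 4 counts of clones against the parent with the treated parent as reference. Genes of shifted chromosomes were also dropped from the 8 counts that involve clones, with the main fit and its adjusted p kept. These counts stayed within 1.5 times too, which shows only how many calls lay on other chromosomes. They were 5196 genes for clone 250:3 and 8230 for 250:7. For the 1000 nM clones from 250:3 and 250:7 they were 9214 and 8947 against the parent, and 9014 and 5422 against their progenitors. Between the 250 nM clones 9395 remained, and 6438 for the interaction. Median log2 changes over all genes lay between -0.012 and 0.038 with TMM and between -0.009 and 0.026 with RLE factors. Numbers of shared calls were recomputed with RLE factors, DESeq2, no filter and the covariate, and stayed within 1.5 times their value. Medians of the shifted chromosomes described below kept their direction with RLE factors. The camera tests of chromosomes were not repeated there, so whether their calls hold was not tested.

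Leaving out single libraries gave 803 to 1160 genes for the treated parent, against 2032 with all 4, where one arm then held 1 library, assumed to vary like the other groups. The counts were 803 without untreated library 2, 1160 without untreated library 10, 1003 without treated library 1 and 1115 without treated library 9. The ranges were 3853 to 4977 for clone 250:3, 6534 to 8045 for 250:7, 8605 to 10853 and 8113 to 9673 for the 1000 nM clones from 250:3 and 250:7 against the parent, 9422 to 10740 and 5003 to 5430 against their progenitors, 9221 to 9357 between the 250 nM clones and 7624 to 8875 for the interaction.

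With an estimated instead of a preset correlation the number of lists called went from 17 to 4 for the treated parent, 9 to 3 for clone 250:3, 14 to 1 for 250:7, and 12 to 2 and 18 to 3 for the 1000 nM clones from 250:3 and 250:7 against the parent. It went from 11 to 1 and 14 to 3 for those clones against their progenitors, from 12 to 0 between the 250 nM clones (1 at an unadjusted camera p under 0.05) and from 9 to 3 for the interaction. A larger correlation between members widens the null distribution of the list. Leaving out single libraries gave 10 (without library 7) to 17 (without library 6) lists for the 250:3 step and 8 (without library 5) to 15 (without library 6) for the interaction.

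Of 690 pairs of a named gene and a comparison, 618 kept their direction and call under every alternative. The 12 that turned did so with the treated parent as reference. These were PKMYT1 (0.39 in clone 250:3 and 0.03 in the 1000 nM clone from 250:3), ABCG2 in 250:3 (0.12), PAPPA2 (-1.33 in 250:3, -1.16 in 250:7, -1.61 and -1.09 in the 1000 nM clones from 250:3 and 250:7), CHAC1 in 250:7 (-0.44), ASNS (-0.45 in 250:7 and -0.97 in its 1000 nM clone) and SESN2 (-1.33 and -1.27 likewise). Each of these genes had itself been called in the treated against the untreated parent, which moves the reference, though the call of ABCG2 there was lost whichever library was left out. Calls were lost in 88 cases on leaving out 1 library, 18 with the treated parent, 3 with the covariate, 2 each with DESeq2 and no filter and 1 in the fit of only the libraries compared. They were gained in 6 cases on leaving out 1 library, 8 without a filter, 5 in the fit of only the libraries compared, 4 with DESeq2 and 1 each with RLE factors and limma. The cause was not tested. No scaling moved the share of rises among calls by over 10 percentage points, but leaving out 1 library did in the treated parent, where it went from 49.1% to 62.3% without treated library 1 and 38.2% without treated library 9. Depth limits genes under 3 counts per library. Bounds are given for groups with 0 counts and intervals for groups with 1 to 3 counts in all, while groups with more, such as THY1 in clone 250:3 (5 counts over 3 libraries), carry the fitted change, whose size is uncertain at so few counts.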

Other observations

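Genes and regions in this part were chosen after their values were seen, and the tests of whole chromosomes are camera tests fixed beforehand, given with an estimated correlation. Protein-coding genes at 5 CPM or more in the untreated parent and at 0.1 CPM or less in a clone numbered 7 in clone 250:3, 14 in its 1000 nM clone, 10 in clone 250:7 and 13 in its 1000 nM clone. Of the 7 in clone 250:3, 5 were also silent in its 1000 nM clone, 0 were silent in clone 250:7, and THY1 (86.7 CPM) and PLEKHA6 (18.4 CPM) were back above 5 CPM in the 1000 nM clone. Of the 10 in clone 250:7, 8 were also silent in its 1000 nM clone. TENM2, NCAM2, SORCS3 and TMPRSS15, silent in both clones of the 250:3 lineage, lay at 57.7, 138, 182 and 184 CPM in clone 250:7, against 42.4, 15.6, 14.9 and 12.1 CPM in the parent. GLUL, at 112 CPM in the parent and 0.0136 CPM in clone 250:7, lay at 190 and 171 CPM in the 250:3 lineage. These are values without a test of their own.

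The median of protein-coding genes with a mean of at least 1 CPM was shifted for some chromosomes in clones, while in the treated parent none lay 0.3 or more (log2) from the median of all genes. Values of whole chromosomes given here are distances from that median of all genes, and values of bins are plain medians. In clone 250:3 genes of chromosome 21 lay at -0.56 (camera adjusted p = 3.7e-05) and of chromosome 13 at -0.35 (0.0368). Chromosome 21 differed between the 250 nM clones by -0.74 (0.000159). From clone 250:3 to its 1000 nM clone it rose by 0.57 (0.00294), and against the parent it lay at 0.06 in that 1000 nM clone (0.567). In the same step chromosomes 18 (-0.63, 0.00294), 8 (-0.56, 0.0143) and 6 (-0.39, 0.0328) fell. On chromosome 8 in that step 57% of genes were called as falls and 29.2% as rises. Against the parent that clone had chromosome 17 at 0.45 and chromosome 8 at -0.68 (0.00611 each). In the 250:7 lineage chromosome 10 lay at -0.65 after the step to 1000 nM (456 genes, 72.6% called as falls, 0.000201) and chromosome 18 at 0.32 (0.0284). Along chromosome 10 the bins up to 40 Mb lay at -0.11 to 0.04, those from 40 to 80 Mb at -1.45 to -0.96, those from 80 to 110 Mb at -0.58 to -0.53, and those from 110 to 140 Mb at -0.97 to -0.81. Against the parent the same clone had chromosome 10 at -0.57 and chromosome 16 at -0.42 (0.0101 each).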
